A study of Dicentrarchus labrax with 53 samples.

How the data were processed

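The series holds 53 samples of European sea bass, 21 measured by RRBS and 32 by RNA sequencing, and 31 RNA libraries were used. DNA was extracted with phenol and chloroform and RNA with Trizol, per the labels' protocols, and RNA libraries were made with a stranded mRNA kit. RRBS libraries of brain, liver and embryos came from one commercial kit, and those of muscle and testis from a custom kit with 100 ng of DNA, per the labels' protocols. Single sites, windows and mean levels were therefore tested only between samples of the same kit. Muscle and testis were set beside brain and liver, across kits, in the pairing of replicate numbers and the embryo position. The fish were 3 years old where farmed, per the labels, and no age is given for wild fish. The design text of the series names separate fish, so replicates were treated as separate fish and their spread as the spread between fish (between pools for embryos), although 2 pairs of wild liver RNA libraries were nearly identical and p-values there measure only the spread between libraries.

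The authors deposited gene counts per RNA library, as whole numbers that were not normalized. Per the submitters' processing notes reads were handled with HISAT2 2.1.0 and featureCounts of the Subread package. The genome build and annotation are not given in the sources used here, nor whether counting used the strand, so reads of overlapping, antisense or near-identical genes are of uncertain origin. For each CpG site and strand the deposited RRBS files give the percent methylation and the coverage in reads, from a coverage of 1 upward. Per the submitters' processing notes BSMAP 2.90 and methylKit were used. Methylated and unmethylated reads were recovered as percent times coverage. The files name 24 linkage groups and a class of unplaced sequence, and 1561874 sites occur in any of them; positions are given as in the files.

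Samples were grouped by the labels. Columns of the count tables carry 1 of 2 codes and a number. The code FLT was taken as farmed because the testis table numbers it to 7, as only farmed testis labels do, and WF as wild. No column stood for wild brain 2, which is not analysed here, so brain was compared with 4 wild libraries where 5 had been foreseen. Another 9 columns of muscle and testis match no sample of this series as given here and were not used. Of 26719 gene identifiers 0 matched the reference gene table of assembly dlabrax2021, so gene lists fixed beforehand were not tested, and methylation near genes was not related to expression.

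Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with robust dispersion, TMM scaling and the genes kept by filterByExpr, at a Benjamini-Hochberg adjusted p under 0.05. Brain and liver were fitted separately for origin, together for the interaction, and the 22 farmed libraries together for tissues, where an absolute log2 fold change over 1 was also required. CPM are counts-per-million, scaled by TMM for genes named in brain and liver and unscaled for the interaction and the tissues. Named genes were those with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups, with the largest log2 fold change in each direction (for tissues at least 100 CPM, for the interaction the smallest p), limited to 2 per direction since no symbols are at hand.

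CpG sites were tested with a logistic model of methylated and unmethylated reads, with overdispersion moderated across sites and never under 1, written for this purpose in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Sites needed a coverage of at least 10 in every sample compared, no coverage above the 99.9th percentile of a sample and a mean methylation of 5 to 95%. A call needed an adjusted p under 0.05 and a difference of at least 25 percentage points (15 for windows of 500 bp with at least 3 sites). Mean methylation was compared by exact two-sided permutation tests. These designs, the thresholds and most alternatives were chosen before the data were examined. The alternatives were other scaling, filters, DESeq2 1.42.0, limma 3.58.1, coverage minimums of 20 and 5, other difference thresholds, summed strands, no overdispersion, the replicate number as a block, and each replicate left out in turn. Chosen after the data had been seen were the fits without liver-enriched genes, with wild brain 5 alone and with near-identical livers summed, the use of sites called without overdispersion for the overlap and the embryo position, and the tissue-abundant lists with their Fisher's exact tests.

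The tests were checked on simulated data made from the real means, library sizes and coverages. For RNA, of 100 genes changed 4-fold (2-fold in brackets), 27 (1) were recovered in brain, 83 (34) in liver and 39 (0) in the interaction, and of the tissues 72 (22) in brain, 70 (24) in liver, 71 (27) in muscle and 82 (29) in testis. For CpG sites, of 1000 changed by 50 points (30 points in brackets), 28.6% (4.1%) were recovered in farmed-wild brain, 76.8% (23.8%) in farmed-wild liver, 41.6% (6.8%) in embryo-brain, 79.6% (24.7%) in embryo-liver, 52.6% (11.5%) in liver-brain, 28% (2.4%) in muscle-testis and 11.8% (1.3%) in the interaction. In the same simulations 6.6 to 9.28% of unchanged sites had an unadjusted p under 0.05. For the tissues each simulated gene had 1 mean over all tissues apart from the change made, so other tissue differences were absent. CpG changes were placed only at sites of intermediate mean methylation, a narrower range than that tested. The recovered shares hold for such data, where this many genes or sites change at once, and can be lower where few do.

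Whether equal replicate numbers pair samples was read from the correlation of their deviations from the group means. In RRBS every pair exceeded 0.1 for muscle and testis (0.194, 0.243 and 0.151), brain and testis (0.174, 0.151 and 0.108), liver and testis (0.290, 0.352 and 0.210) and liver and muscle (0.152, 0.200 and 0.123) of farmed fish, and for brain and liver of wild fish (0.150, 0.162 and 0.203). These numbers were taken to pair the samples, a pairing read from the data and not stated in the labels. Brain and liver of farmed fish (0.150, 0.065 and 0.048) and brain and muscle (0.097, 0.098 and 0.059) did not meet this directly. Each of these tissues paired with testis, which, if it holds, makes equal numbers the same fish there as well. Each brain sample also correlated best with the liver and the muscle sample of its own number. Since the direct values were low, whether equal numbers stand for the same fish there is left open. Embryos against tissues did not meet it. Farmed against wild samples of the same number, which are different fish, did not meet it at every number either. They gave 0.093, 0.206 and 0.0097 in brain and 0.055, 0.220 and 0.109 in liver. Some of these are as high as values taken to pair, so such correlations can arise without shared fish.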

Results

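The series followed the European sea bass (Dicentrarchus labrax), a marine teleost that is both fished and farmed, in hatchery-born fish kept in captivity and in fish caught in the sea. DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads CpG sites close to the cutting sites of a restriction enzyme and therefore samples CpG-dense sequence. It covered brain and liver of 3 farmed and 3 wild fish, muscle and testis of 3 farmed fish, and 3 pools of 5 eggs from captive spawners taken 27 to 30 h after fertilisation. Gene expression was measured by RNA sequencing in libraries of brain (5 farmed and 4 wild), liver (5 farmed and 5 wild), muscle (5 farmed) and testis (7 farmed). Wild tissues had been kept in a preserving solution and farmed tissues snap-frozen, so storage and origin cannot be told apart in any farmed-wild comparison. Farmed fish were 3 years old and no age is given for wild fish, so age cannot be told apart from origin there either. Total counts per RNA library, in units of M (10 raised to the power 6), were 22.3 to 31.5 in farmed brain, 20.001 to 34.4 in wild brain, 29.1 to 35.7 in farmed liver, 22.4 to 38.7 in wild liver, 14.5 to 21.7 in muscle and 13.2 to 21.7 in testis. An RRBS sample held 625666 to 1325785 sites with a median coverage of 9 to 49 reads, and 307199 to 933429 of them had a coverage of at least 10, the fewest in wild liver 2 and the next fewest, 340471, in farmed liver 2. Genes are given by the identifiers of the count tables, none of which is paired with a symbol here.

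Brain expression was compared to ask whether gene activity differs between fish raised in captivity and wild fish. Of 20072 genes tested, 223 were lower and 10 higher in farmed than in wild brain. Genes abundant in liver made up most of the lower group. A list of 306 genes with at least 100 CPM (counts-per-million) in farmed liver, and at least 20 times their levels in farmed muscle and testis, held 175 of the 223 genes, against 3.17 for a random draw from the genes tested. Of the corresponding muscle list 0 and of the testis list 1 were among the 223.

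The gene DLAgn_00083020 rose in farmed brain to 212 ± 69.3 scaled CPM (SD, n = 5) from 42.5 ± 7.23 (n = 4) in wild brain, a log2 fold change of 2.32 (SE 0.32, edgeR adjusted p = 0.00796). DLAgn_00059070 rose to 7.99 ± 3.99 from 1.63 ± 0.37 scaled CPM (log2 fold change 2.29, SE 0.45, edgeR adjusted p = 0.0499). DLAgn_00014250 fell to 0.043 ± 0.074 scaled CPM (5 counts over the 5 libraries) from 19.3 ± 21.6 (2026 counts over 4), a log2 fold change of -8.75 (SE 1.39, edgeR adjusted p = 0.0176). DLAgn_00211470 fell to 3 counts over all farmed libraries from 1273 in wild ones, which stood at 12.02 ± 12.4 scaled CPM (SD, n = 4), from 0.473 in wild brain 1 to 24.8 in wild brain 3 (edgeR adjusted p = 0.0171). The ratio of wild to farmed over pooled counts was 489, with a 95% interval of 167 to 2372 that covers counting error and not this spread between libraries. DLAgn_00059070, DLAgn_00014250 and DLAgn_00211470 were among the genes called higher in liver than in the other farmed tissues, and DLAgn_00083020 was not. The call of DLAgn_00083020 held whichever library was left out. The call of DLAgn_00059070 was lost without farmed brain 1, 2, 3 or 5 or wild brain 1, 3, 4 or 5 (edgeR adjusted p from 0.0839 to 0.151), that of DLAgn_00014250 without farmed brain 1, 2, 4 or 5 or wild brain 4 (0.0515 to 0.0694) and that of DLAgn_00211470 without any 1 of the 5 farmed libraries (0.0537 to 0.0642).

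The liver-abundant genes differed between the wild brain libraries themselves. All 306 list genes together took 1.9997% of the counts in wild brain 1 (95% Wilson interval 1.995 to 2.004), 3.59% in wild brain 3 (3.580 to 3.594), 4.47% in wild brain 4 (4.466 to 4.480) and 0.971% in wild brain 5 (0.9668 to 0.9754), intervals that cover counting error only. In the 5 farmed brain libraries they took 0.291 to 0.738%, in farmed liver 55.8 to 66.1% and in wild liver 65.2 to 67.5%. The 194 of them that were picked for standing in farmed brain at under 0.1% of their liver level took 1.04, 2.05, 2.08 and 0.210% in wild brain 1, 3, 4 and 5. The overlap of 175 genes exceeded chance in a two-sided Fisher's exact test (p = 6.27e-305, 1.88e-304 after Benjamini-Hochberg adjustment over 3 lists), whereas the muscle list, with 85 genes tested, and the testis list, with 146, did not (p = 1 and adjusted p = 1 for each). The lists were set from farmed liver, muscle and testis alone, after the 223 genes had been counted, and genes of a list do not vary independently.

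**Figure D1:**
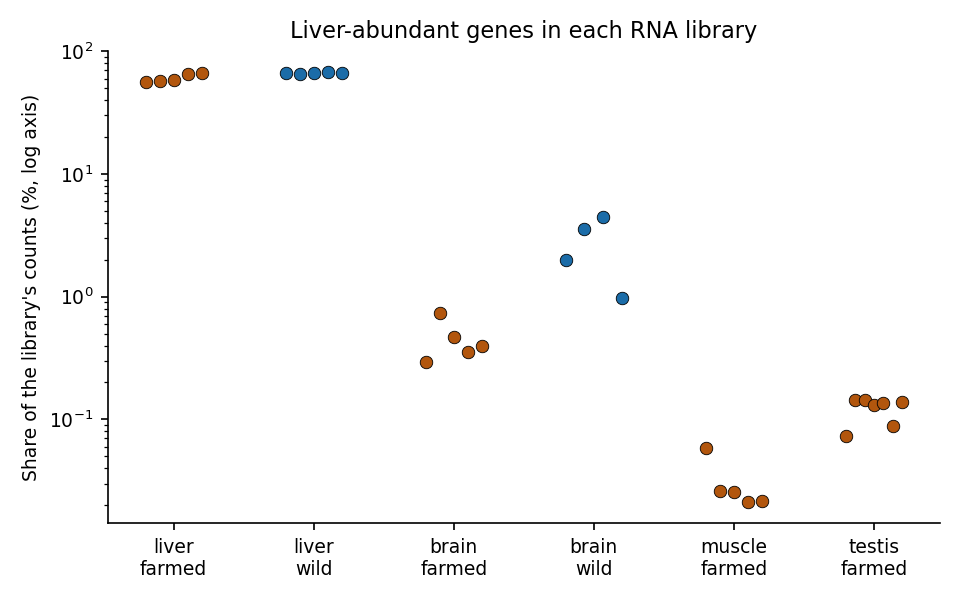
Percent of all RNA counts (log axis) in the 306 liver-abundant genes, with 1 point for each library of brain, muscle, testis and liver by origin. The wild brain libraries lie at 0.971 to 4.47%, above every farmed brain library (0.291 to 0.738%) and below every liver library (55.8 to 67.5%).

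Counts of genes in brain come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, and 2306 genes had an unadjusted p under 0.05. The count was 143 without farmed brain 1, 146 without farmed brain 5 and 153 without wild brain 4, DESeq2 called 966 genes (282 higher, 684 lower) and edgeR with brain and liver in one fit 583 (58 higher, 525 lower). When the genes that were higher in liver than in the other farmed tissues were left out, edgeR called 0 of 16341 genes (1615 at an unadjusted p under 0.05), and with wild brain 5 as the only wild library, whose spread is then taken to be that of the farmed libraries, it called 0 of 21594 (1489 at an unadjusted p under 0.05). The called genes still tested kept their sign in both fits. In the first, median log2 fold changes were 1.6005 for 6 higher genes (1.67 before) and -1.56 for 16 lower ones (-1.50 before), all with an unadjusted p under 0.05. With wild brain 5 they were 1.83 for 10 higher genes (median SE 0.47, from 1.67 and 0.27), 9 of them with an unadjusted p under 0.05, and -3.55 for 217 lower ones (median SE 0.85, from -6.29 and 0.84), 183 of them so. DLAgn_00083020 stood at 2.26 (SE 0.32, edgeR adjusted p = 0.224) and 2.27 (SE 0.68, edgeR adjusted p = 0.566). The genes followed had been called from these same libraries, with no overlap between groups. Their kept signs and small unadjusted p-values were therefore largely fixed in advance and give no support to a difference by origin. Neither fit was repeated with DESeq2, and both were added after the data had been seen.

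Expression in liver was compared for the same question. Of 15527 genes tested, 1627 were higher and 1706 lower in farmed than in wild liver, and 1837 of these differed at least 2-fold, 918 upward and 919 downward. DLAgn_00151920 was nearly silent in wild liver, at 0.25 ± 0.17 scaled CPM (SD, n = 5), and reached 245 ± 146 (n = 5) in farmed liver, a log2 fold change of 9.83 (SE 0.83, edgeR adjusted p = 0.000219). DLAgn_00124320 rose to 130 ± 137 from 0.65 ± 0.54 scaled CPM (log2 fold change 7.71, SE 1.07, edgeR adjusted p = 0.00233). In the other direction, DLAgn_00266560 fell to 0.079 ± 0.080 from 11.3 ± 11.6 scaled CPM (log2 fold change -7.17, SE 0.84, edgeR adjusted p = 0.00113) and DLAgn_00239160 to 0.48 ± 0.62 from 50.8 ± 26.3 (log2 fold change -6.72, SE 1.04, edgeR adjusted p = 0.00347). All 4 genes kept their call in each of the 68 alternative fits made of them. The 10 most abundant genes of a library took 25.8 ± 1.57% of its counts in farmed liver (SD, n = 5) and 31.6 ± 0.77% in wild liver (n = 5).

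The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05 (5783 genes at an unadjusted p under 0.05). Without scaling beyond the library total the median log2 fold change of all genes moved to 0.43, from 0.01, and the split became 4719 genes higher and 484 lower. Wild liver 1 and 5 were nearly identical, with a chi-square per degree of freedom of 3.86 over genes, as were wild liver 2 and 3, with 4.44. Other pairs of wild livers gave 93.8 to 119 and pairs of farmed livers at least 101.5. Both close pairs still differed by more than sampling noise and were kept as separate libraries, which does not show that they came from separate fish, so n = 5 for wild liver counts libraries. With each pair summed to 1 library, which leaves 3 wild livers, 580 genes were called (232 higher, 348 lower), of which 576 were among the 3333.

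Whether the farmed-wild difference itself differed between liver and brain was tested as an interaction over all 19 libraries of these tissues. It did so for 1098 of 21106 genes, with the liver difference above the brain difference in 769 and below it in 329. Of the 1098 genes 565, and of the 769 genes 520, were higher in liver than in the other farmed tissues, DLAgn_00158270 among them. Liver RNA in the wild brain libraries, weighed below, would move such genes in the direction of the 769. DLAgn_00158270 stood at 285 ± 55.5 CPM of the library total in farmed liver (SD, n = 5) and 283 ± 27.5 in wild liver (n = 5), while brain held 1 count over the farmed libraries and 810 over the wild ones, at 1.4999 to 11.9 CPM per wild library, a ratio of pooled counts of 933 with a 95% interval, for counting error alone, of 167 to 36879 (edgeR interaction adjusted p = 3.01e-05). DLAgn_00183700 differed in liver, with 319 ± 83.3 CPM in farmed and 19.9 ± 2.92 in wild fish, while brain held 17.6 ± 3.53 (n = 5) and 20.1 ± 4.61 (n = 4), giving a log2 interaction of 3.94 (SE 0.38, edgeR adjusted p = 3.01e-05). DLAgn_00029830 had 0 counts in farmed liver and 364 in wild liver, at least 133-fold higher in wild liver against a floor of 3 counts over the group, while its brain levels were 49.9 ± 5.66 CPM in farmed and 56.2 ± 11.98 in wild fish (edgeR interaction adjusted p = 1.21e-08). DLAgn_00205630 stood at 2.37 ± 0.99 CPM in farmed and 53.8 ± 34.8 in wild liver, and at 50.2 ± 4.99 in farmed and 44.0 ± 7.30 in wild brain (log2 interaction -5.00, SE 0.53, edgeR adjusted p = 4.14e-05).

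The interaction was tested with edgeR's quasi-likelihood test, and the 4 genes kept their call in all 98 alternative fits made of them. The count fell to 688 without wild brain 4, rose to 1844 without farmed liver 1 and was 2266 with DESeq2. Without the genes higher in liver than in the other farmed tissues it was 339 (144 above, 195 below), and with the near-identical wild livers summed 499, both fits added after the data had been seen. Of 14919 genes tested in both tissues, 92 were lower in farmed fish in both brain and liver, where independent lists would share 23.7, and 4 were higher in both, where they would share 0.95. The wild brain libraries carried the liver-abundant genes at the shares given above.

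The farmed tissues were then compared with each other, each against the mean of the other 3, over 22149 genes. In brain 6023 genes were higher and 5430 lower, in liver 4246 and 6872, in muscle 4828 and 4992, and in testis 6984 and 2553. The genes higher in a tissue took 90.6 ± 2.60% of the counts in muscle (SD, n = 5), 87.2 ± 2.18% in liver (n = 5), 48.5 ± 2.77% in brain (n = 5) and 30.0 ± 2.02% in testis (n = 7). Of the genes higher in a tissue, 1286 in brain, 777 in liver, 575 in muscle and 617 in testis stood at 100 CPM or more there.

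The muscle genes with the largest fitted fold change were DLAgn_00086170, at 9457 ± 3033 CPM of the library total (SD, n = 5) and under 6 in every library of the other tissues, and DLAgn_00156950, at 12031 ± 2280. The liver gene DLAgn_00180450 stood at 1104 ± 1200 CPM and DLAgn_00034590 at 1185 ± 967 (n = 5), with no library of another tissue above 0.813. In brain DLAgn_00041050 stood at 5324 ± 4872 CPM (n = 5), and DLAgn_00195950 at 24180 CPM in farmed brain 3 but only 1.87 to 6.59 in the other 4 libraries. The testis genes were DLAgn_00083310, at 5132 ± 4462 CPM (n = 7) against 11.3 ± 19.5 in muscle (n = 5), and DLAgn_00062280, at 249 ± 298. The log2 fold changes against the other tissues were 19.33 (SE 0.65) and 18.98 (SE 0.51) for the muscle genes, 16.69 (SE 0.87) and 16.30 (SE 0.77) for the liver genes, 15.41 (SE 0.61) and 17.79 (SE 2.01) for the brain genes and 10.87 (SE 0.93) and 10.14 (SE 0.97) for the testis genes in the order named, with edgeR adjusted p between 1.17e-17 and 3.9e-07. The calls required an adjusted p under 0.05 in edgeR's quasi-likelihood test and an absolute log2 fold change over 1. Without farmed brain 3 the log2 fold change of DLAgn_00195950 was 7.57 (edgeR adjusted p = 2.21e-08). Where other tissues hold few or no counts the fitted fold change depends on the prior count and is no bound.

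Methylation of brain was compared between origins to ask whether captivity is accompanied by changes at single CpG sites. No site passed: 0 of 224828 tested sites were called, and the smallest adjusted p was 0.0639. Mean levels of farmed and wild brain differed by at least 25 percentage points at 14371 sites, and the groups did not overlap at 9.66% of the tested sites, where chance gives 10% for 3 fish against 3. Of 33222 windows of 500 bp, 0 were called as well. The test was a quasi-binomial logistic model of methylated and unmethylated reads, in which 17127 sites and 2382 windows had an unadjusted p under 0.05. These sites were 7.62% of those tested, against 7.15% of the unchanged sites in the simulation of this comparison. Limma on log ratios also called 0 sites (12495 at an unadjusted p under 0.05). Without farmed brain 2 there was 1 called site, lower in farmed fish, without wild brain 1 there was 1 called window, and a test that ignored the spread between fish called 13815 sites and 3578 windows.

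In liver 1 site was called among 88233, at position 20017971 of linkage group LG9 on the forward strand. It was methylated at 98.2 ± 3.08% in farmed liver and 7.16 ± 9.69% in wild liver (SD, n = 3 each), 91.1 points higher in farmed fish, with adjusted p = 0.0468 in the quasi-binomial model across all sites and no permutation of 3 against 3 fish able to go below 0.1. The values were 94.7, 100 and 100% in the farmed fish and 0, 18.2 and 3.29% in the wild fish, at coverages of 11 to 152 reads, and the gene content at this position was not analysed here. The groups did not overlap at 12.4% of sites, against 10% by chance, and 2959 sites differed by at least 25 points. Of 10914 windows of 500 bp 0 were called by the same model (847 at an unadjusted p under 0.05), and 546 when the spread between fish was ignored.

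At an unadjusted p under 0.05 the model found 6451 liver sites. They were 7.31% of those tested, against 9.28% of the unchanged sites in the simulation of this comparison. Unchanged liver sites thus passed more often than the 0.05 threshold allows, which limits the call on LG9. Median coverage was 17, 25 and 26 reads in farmed liver 1 and 3 and wild liver 3, and 9 to 11 in the other 3 livers. Either depth alone held too few fish of each origin for a test. Origin was not tested with depth as a further term. Leaving out farmed liver 1, 2 or 3 or wild liver 2 or 3 gave 0 called sites (6661 to 7655 at an unadjusted p under 0.05), leaving out wild liver 1 gave 7, and limma gave 0 (4339 at an unadjusted p under 0.05). A minimum coverage of 20 or of 5 reads and the inclusion of every varying site also gave 0 (3048, 10774 and 12774 at an unadjusted p under 0.05), whereas no upper limit on coverage gave 10, summed strands 5 and a test that ignored the spread between fish 2702.

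The farmed-wild difference in methylation did not detectably differ between liver and brain, since 0 of 75754 sites were called in the interaction of the quasi-binomial model (3789 at an unadjusted p under 0.05) and 0 by limma (3388 at an unadjusted p under 0.05). A test that ignored the spread between fish called 3430. There were 2 calls without wild liver 1, 1 without farmed brain 1 and 1 without wild brain 2. With 0 called sites in brain, the called sites of the tissues could not overlap. Across the 55724 sites tested in both, which are not independent replicates, the brain and liver differences had a Pearson correlation of 0.187 and a Spearman correlation of 0.112. Sites called when the spread between fish was ignored, a choice added after the data had been seen, overlapped at 147 sites higher in farmed fish, where independent lists would share 12.5, and at 216 lower sites, where they would share 24.1. Independent lists leave out that brain and liver of the same number deviated together among the wild fish, and regroupings of the same numbered fish in both tissues gave Pearson correlations of 0.108 to 0.219, a range that holds the real 0.187.

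Embryos were compared with brain of farmed fish, which was prepared with the same kit, to describe how methylation differs between an early stage and an adult tissue. At 53219 of 199004 sites the embryos differed from brain, and at 47771 of these they were the more methylated. Those sites were almost fully methylated in embryos, at 97.0 ± 0.097%, and partly methylated in brain, at 43.3 ± 7.16% (SD over samples, n = 3 each). The 5448 sites lower in embryos stood at 17.6 ± 0.90% in embryos and 61.8 ± 6.23% in brain. A minimum coverage of 20 left 32970 called sites of 123445. Of the tested sites the share called ran from 30.6% on linkage group LG19 to 38.9% on LG24, and was 10.7% on unplaced sequence.

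Intermediate methylation was rare in embryos. Among sites with a coverage of at least 10, 5.90 ± 0.15% lay between 20 and 80% methylation in embryos (SD, n = 3), against 19.3 ± 3.18% in farmed brain, 21.9 ± 1.68% in wild brain, 20.8 ± 2.14% in farmed liver, 15.2 ± 1.03% in wild liver, 19.8 ± 0.88% in muscle and 16.1 ± 0.69% in testis (n = 3 each). Muscle and testis were prepared with another kit than the other samples, and an embryo sample is a pool of 5 eggs. These shares were not tested.

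**Figure D2:**
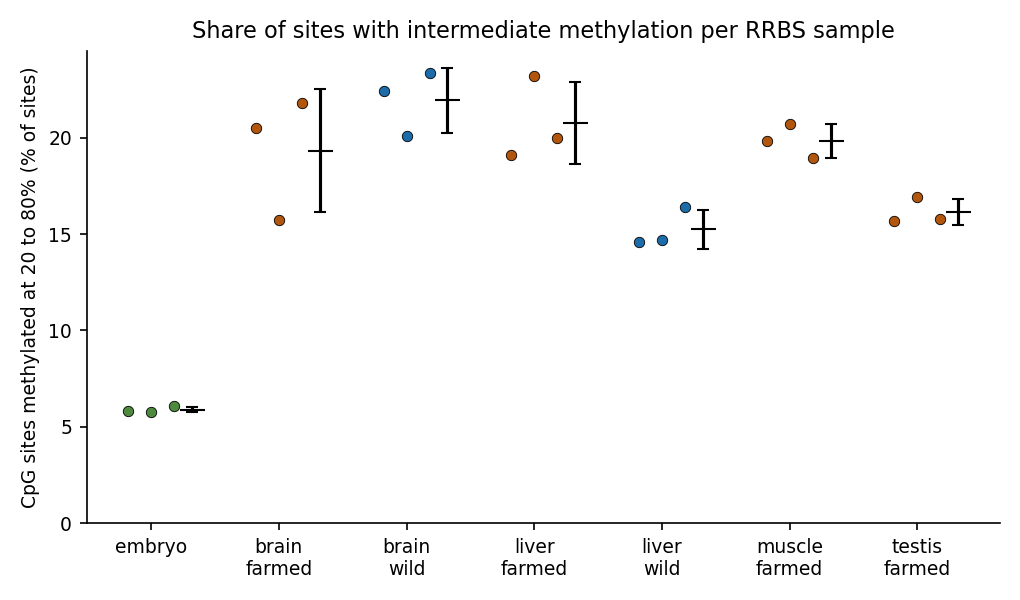
Percent of CpG sites (coverage of at least 10) with a methylation of 20 to 80%, from 0 upward, for each RRBS sample (points) with the mean ± SD of each group of 3. The 3 embryo pools lie at 5.78 to 6.06%, below every tissue sample.

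Against liver of farmed fish 12303 of 89927 sites were called, 10663 of them higher in embryos, where they stood at 95.2 ± 0.21% against 51.0 ± 5.62% in liver (SD over samples, n = 3 each), and 1640 lower, at 20.1 ± 0.78% against 63.6 ± 0.70%. The share called ran from 15.7% on LG3 to 27.6% on LG18-21, with 6.45% on unplaced sequence. The count was 38349 without farmed liver 2, the sample of lowest coverage in that group, when 229190 sites could be tested, 5366 and 20157 at a minimum coverage of 20 and 5, and 26220 with a difference of at least 15 points. Of the 51766 sites tested against both tissues, 4625 were higher in embryos against both, where independent lists would share 1664, and another 715 were lower against both, where they would share 28.6. Unchanged groups simulated against the same embryo pools shared 0, but the model called 0 sites against either of them, so this does not measure what shared pools add. Part of these excesses may come from the embryo pools that both comparisons use. Both embryo comparisons used the quasi-binomial model with an adjusted p under 0.05 and a difference of at least 25 points, and had 99196 sites (brain) and 52324 sites (liver) at an unadjusted p under 0.05.

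Liver and brain of farmed fish differed at 4609 of 100405 sites, of which 3914 were more methylated in liver. These stood at 87.6 ± 0.50% in liver and 31.3 ± 8.80% in brain (SD over samples, n = 3 each), and the 695 sites lower in liver at 35.5 ± 1.26% and 84.3 ± 3.10%. The share called was lowest on LG19, at 6.14%, and highest on LG20, at 11.2%, with 1.03% on unplaced sequence. By the quasi-binomial model 26814 sites had an unadjusted p under 0.05, and limma called 1095, a minimum coverage of 20 left 2022 and a test that ignored the spread between fish called 15253. With the replicate number as a block, which leaves fewer residual degrees of freedom, the model called 0 sites (26425 at an unadjusted p under 0.05). This 0 does not show that the tissues are alike. Brain and liver of the same number deviated together by over 0.1 in only 1 of the 3 pairs, but each of these tissues did so with testis in all 3. If these ties to testis stand for shared fish, brain and liver are paired as well, and the fit with the block is the one that applies. The count was 1931 without liver 1, 0 without liver 2 (51138 of 248372 at an unadjusted p under 0.05), 667 without liver 3 and 1448 without brain 3.

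Muscle and testis of farmed fish differed at 23265 of 374697 sites, with testis the more methylated at 17095. Sites lower in muscle stood at 37.5 ± 0.83% in muscle and 85.4 ± 0.90% in testis, and the 6170 higher ones at 86.5 ± 0.92% and 42.6 ± 3.24% (SD over samples, n = 3 each). The share called ran from 6.62% on LG5 to 10.2% on LG18-21, with 1.84% on unplaced sequence. Samples of the same number deviated together in these tissues, and with the number as a block the quasi-binomial model called 0 sites (91123 at an unadjusted p under 0.05, against 84277 without the block). The block leaves fewer residual degrees of freedom, so this 0 does not show that the tissues are alike. Limma without the block called 7832, a test that ignored the spread between fish 52385, and the count was 6893 without testis 1, 0 without testis 2 (58584 at an unadjusted p under 0.05) and 6908 without testis 3.

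Mean methylation was compared over the sites covered at least 10 times in every sample of both groups. Embryos stood at 64.7 ± 0.13% against 56.8 ± 1.39% in brain, and at 65.0 ± 0.14% against 58.5 ± 2.06% in liver (SD, n = 3 each, farmed fish), with every embryo pool above every tissue sample. Muscle stood at 60.1 ± 0.37% against 63.8 ± 0.63% in testis, with no overlap. Each of these 3 comparisons gave p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 samples allow, and an adjusted p = 0.2 over 6 comparisons. Farmed and wild brain both stood at 55.4%, with SDs of 1.37 and 0.23 (n = 3 each, exact p = 1, adjusted p = 1). Farmed liver stood at 57.8 ± 2.06% and wild liver at 59.0 ± 0.026% (exact p = 0.2, adjusted p = 0.3), and liver and brain of farmed fish at 57.1 ± 1.91 and 56.8 ± 1.43% (exact p = 1, adjusted p = 1). Over each sample's own sites the farmed-wild difference turned from -0.012 to 1.005 points in brain and from -1.26 to 0.852 in liver, and the liver-brain difference turned from 0.304 to -0.698 points at a minimum coverage of 20. Without farmed brain 3 or wild brain 1 the farmed-wild difference in brain was 0.836 or 0.107, without farmed liver 2 that in liver was -0.134, and without liver 3 or brain 3 the liver-brain difference was -0.149 or -0.296.

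**Figure D3:**
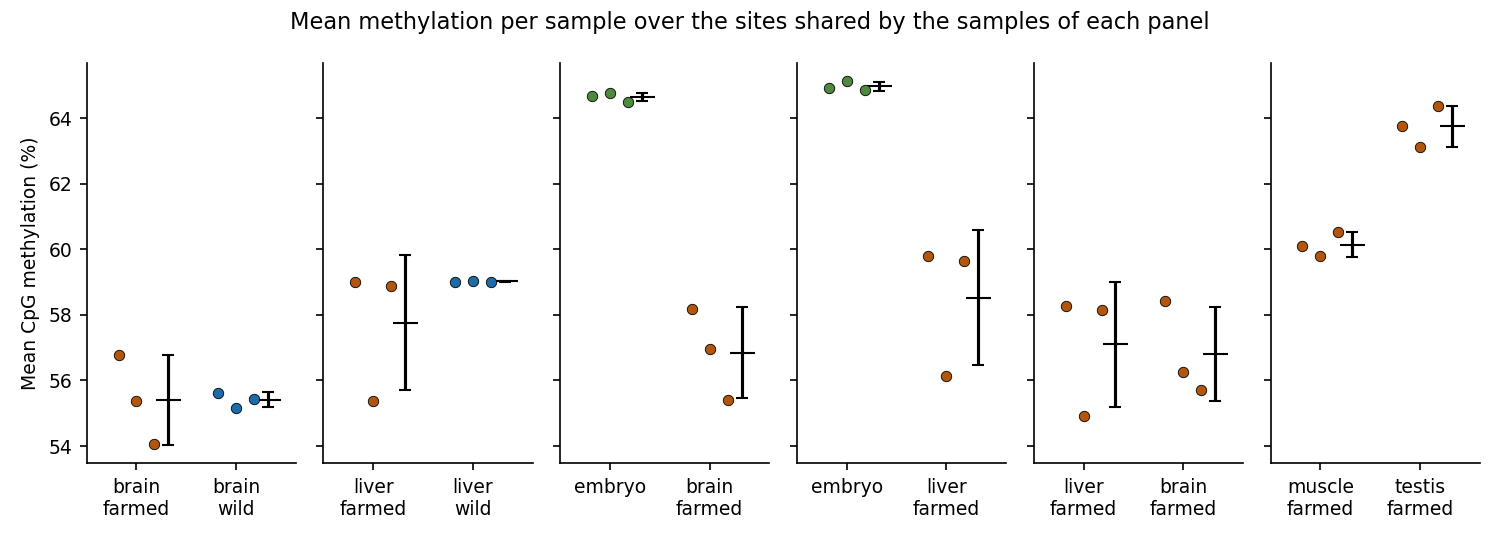
Mean CpG methylation in percent over sites covered at least 10 times in every sample of the groups compared, in 6 panels of 2 groups, with points for samples and the mean ± SD (n = 3). Embryos lie above brain (64.7 against 56.8%) and liver (65.0 against 58.5%), and testis above muscle (63.8 against 60.1%), while farmed and wild fish overlap in brain and in liver.

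Embryos of captive spawners were placed between the farmed and wild levels at sites that differ with origin. Brain had 0 called sites, so it gave no position. At the liver site on LG9 all 3 embryo pools were closer to farmed liver, at 72.7, 97.8 and 93.5% methylation with coverages of 77, 45 and 46 reads. At sites called when the spread between fish was ignored, a choice added after the data had been seen, embryos were closer to the farmed mean at 48.2 ± 0.20% of sites for brain and 48.7 ± 1.52% for liver, as a mean over both directions (SD, n = 3). Farmed muscle gave 51.7 ± 1.12 and 62.0 ± 2.79%, and farmed testis 50.3 ± 1.41 and 64.0 ± 3.56%, at brain and liver sites. Muscle and testis were made with another kit than brain and liver. Liver deviated together with muscle and with testis of the same number, as did brain with testis, so the closeness of both tissues at liver sites, and of testis at brain sites, is not independent of the farmed fish compared. Within each direction the embryo pools were closer to farmed fish at 85.1 ± 0.79% of the brain sites higher in farmed fish and at 11.3 ± 0.42% of those lower. Farmed testis gave 74.5 ± 2.72 and 26.1 ± 0.69%, and farmed muscle 64.1 ± 2.21 and 39.2 ± 1.11%. At liver sites the embryo pools gave 78.8 ± 2.36 and 18.6 ± 1.93%. Their position at the LG9 site, which is higher in farmed fish, therefore depends on the direction of that site. Whether the higher methylation of embryos underlies this was not tested.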

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

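The tests of liver RNA in wild brain, near-identical wild livers and recovery in simulations, the fits without liver-enriched genes, with wild brain 5 alone or with near-identical livers summed, and the counts over splits of the samples for single CpG sites were chosen only after their results were seen. The test of liver RNA first gave 99% over the 100 most abundant list genes that farmed brain lacks, a choice of genes that favours a high share, and was moved to all 306 list genes after their 80.4% had been seen, which lies only just above the 80% it was held to.

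Among 63 sets of library values examined, 9 held a library far from the others of its group, where chance gives about 1 in 20. Muscle 4 had 21.7 M counts (M, 10 raised to the power 6), the other muscle libraries 14.5 to 16.4. Muscle 1 held 0.0231% of its counts in the 194 liver-abundant genes that farmed brain holds at under 0.1% of their liver level, the others 0.00679 to 0.0101%. DLAgn_00083020 stood at 91.5 scaled CPM in farmed brain 2 and 215 to 261 in the other farmed brains, and DLAgn_00014250 at 0.170 in farmed brain 3 against 0 to 0.0448. DLAgn_00266560 stood at 32.0 scaled CPM in wild liver 4 and 5.20 to 7.67 in the other wild livers. DLAgn_00158270 stood at 0.0428 CPM in farmed brain 2, from 1 count, and 0 in the others, and at 186 in farmed liver 5 against 307 to 312. DLAgn_00195950 reached 24180 CPM in farmed brain 3 against 1.87 to 6.59, and DLAgn_00041050 13997 in farmed brain 2 against 2476 to 3781. The farmed-wild difference differed between liver and brain, in a test of the difference itself, for 1098 genes.

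For the genes lower in farmed brain, RNA of all tissues mixed into the wild brain libraries is argued against, since 3.23% of all 186 muscle-abundant genes, and 3% of the 100 most abundant that farmed brain lacks, were higher in wild brain 1, 3 and 4 than in every farmed brain, although 61 of the 186 and 40 of the 100 were in wild brain 5 (16.7% for exchangeable libraries). Liver RNA in the wild brain libraries is a candidate explanation. Of all 306 liver-abundant genes, unfiltered on brain, 80.4% were higher in all of wild brain 1, 3 and 4 (1.79% for exchangeable libraries) and 0 lower. In wild brain 5, 243 were higher. The most abundant of the 194 at under 0.1% of their liver level in farmed brain, at 25112 CPM in farmed liver, stood at 1593, 1858, 3051 and 342 in wild brain 1, 3, 4 and 5. Its low level in farmed brain, at most 27.6, follows from how the 194 were picked. Whether such liver RNA came from the same fish stays open, as 3 of 4 wild brains ranked genes of the 194 most like the liver of their own number or its near-identical partner, where 4 were needed. Of 100 splits of the 9 brain libraries 3, the real one included, gave as many genes as the real 233, a share under 0.05. The highest other split gave 1805, which points to a structure of the samples beyond origin, so this count does not exclude chance. A difference in brain expression by origin, storage or age stays open. Without the liver-enriched genes edgeR called 0 genes (1615 at an unadjusted p under 0.05). The 6 higher and 16 lower genes left in that fit had median log2 fold changes of 1.6005 (median SE 0.28) and -1.56 (0.26), from 1.67 (0.27) and -1.50 (0.25). All kept their sign and an unadjusted p under 0.05. They had been called from the same counts, so this was fixed in advance and gives no support to a difference. Their calls ended (adjusted p 0.224 to 0.331) as the other called genes, left out by construction, no longer lent small p-values to the adjustment. The count of 0 therefore does not show that a difference is absent. Farmed brain was among the tissues that set the liver-enriched genes, so a low level in farmed brain itself helped a gene to be left out.

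The genes called in liver are weighed next. Genes abundant in brain, muscle or testis, the other tissues at hand, and low in liver were 141 of the 3333 called genes (4.23%). They were 801 of the 15527 genes tested, so the called genes did not hold a larger share of them. With only 801 tested, they could not have made up most of the called genes, which was the bar set. Cells of another tissue in the liver libraries therefore stay open. Near-identical wild livers counted as separate fish may account for part of the count, as 17.3% of the called genes were still called with the pairs summed to 3 wild libraries, so the effect of counting a fish more than once and that of fewer libraries cannot be told apart. Of 100 splits 1, the real one, gave as many as the real 3333 (highest other 811), but these splits treated the near-identical libraries as separate. With the pairs summed 2 of 56 gave as many as the real 580, and the highest other, 764, exceeded it. Neither count therefore excludes chance. Captive or wild origin, the storage that went with it and any difference in age stay open, as untested.

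For the few CpG sites called between origins, too little power is a candidate explanation in brain. There the test recovered 28.6% of simulated differences of 50 points. This explanation stays open in liver, where 76.8% of these and 23.8% of differences of 30 points were recovered. The simulations changed 1000 sites of each size at once, which eases the adjustment, so recovery can be lower where few sites differ. They also changed only sites of intermediate mean methylation, so recovery at other sites was not measured. Fish differing from each other as much as origins do is consistent with the 14371 brain sites that differed by at least 25 points, within the 10583 to 17889 of the other 9 splits. For liver, a split of farmed 1 and 3 with wild 3 called 391 sites where the real split called 1, and it parts the 3 livers of deeper coverage (medians of 17, 25 and 26 reads, mean methylation of 61.8 to 62.7% over each one's sites covered at least 10 times) from the 3 of lower coverage (9 to 11 reads, 55.2 to 58.8%), so depth or mean level goes with this structure of the samples and origin does not. An effect of origin that is small or at few sites stays open.

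The other counts were set against splits of the same samples in the same way. For the interaction in RNA 1 of 100 splits, the real one, reached 1098 (highest other 517). These splits treated the near-identical wild livers as separate, and none were run with the pairs summed, so chance is not excluded there. For the tissues only the real split reached the real count, a share under 0.05 (1 of 40 each, with 11453 genes and a highest other of 1433 in brain, 11118 and 1190 in liver, 9820 and 3724 in muscle, and 9537 and 1931 in testis). With 40 splits the share could not be lower than 1 of 40. The splits also leave out that tissues may come from the same fish. A real count of 0 is reached by every split, which says nothing about chance: this holds for the CpG interaction (100 of 100 splits, highest other 32), brain sites (10 of 10, highest other 1), brain windows (10 of 10, highest other 0) and liver windows (10 of 10, highest other 1). For the rest the 10 splits of 3 samples against 3 are too few for a share under 0.05. There the real and highest other counts were 1 and 391 for liver sites (as many in 3 splits), and 53219, 12303, 4609 and 23265, each against 0 (1 split), for embryo-brain, embryo-liver, liver-brain and muscle-testis sites. The splits leave out the pairing by replicate number, and with the number as a block the liver-brain and muscle-testis counts were 0, in fits with fewer residual degrees of freedom.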

How the results depend on the processing

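Fits without liver-enriched genes, with wild brain 5 alone or with near-identical livers summed, and the use of sites called without overdispersion for the overlap and embryo position, were chosen only after the results were seen. Of the alternatives tried, the counts of the 4 tissue comparisons stayed within 1.5 times in all 26 each. Counts of farmed-wild genes did so in 10 of 18 for brain, 14 of 18 for liver and 20 of 25 for the interaction, and counts of sites in 13 of 15 for farmed-wild brain, 1 of 15 for farmed-wild liver, 14 of 15 for embryo-brain, 10 of 15 for embryo-liver, 7 of 15 for liver-brain, 9 of 15 for muscle-testis and 17 of 21 for the CpG interaction. Named genes, where tested, kept their call except in 29 of 65 fits for brain, and none changed sign. Where no reason is given, the cause was not tested. Depth limits sites most in liver, where farmed 2 and wild 2 hold the fewest sites at a coverage of 10. Gene lists and methylation near genes were not run, having no symbols or coordinates, and embryo position gave no value for windows or at a coverage of 20.

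DESeq2 called 966 genes in brain and 2266 in the interaction. One fit of brain and liver gave 583 in brain. A log2 threshold of 1 left 1837 in liver, fewer by construction, and library totals without scaling gave 5203. Without liver-enriched genes edgeR called 0 in brain (1615 at an unadjusted p under 0.05) and 339 in the interaction, with wild brain 5 alone 0 in brain (1489), and with near-identical livers summed, which leaves fewer samples, liver had 580 and the interaction 499.

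With no overdispersion the counts were 13815 for brain sites, 2702 for liver sites, 15253 for liver-brain, 52385 for muscle-testis, 3578 for brain windows, 546 for liver windows and 3430 for the CpG interaction, as that test leaves out the spread between fish. Limma gave 0 in liver (4339 at an unadjusted p under 0.05), 1095 in liver-brain and 7832 in muscle-testis. In the quasi-binomial model a coverage of 20 gave 0 in liver (3048 at an unadjusted p under 0.05), 32970 in embryo-brain, 5366 in embryo-liver and 2022 in liver-brain, with fewer sites tested, and a coverage of 5 gave 0 in liver (10774) and 20157 in embryo-liver. In liver no upper coverage limit gave 10, all varying sites 0 (12774) and summed strands 5. A difference of 15 points gave 26220 in embryo-liver.

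With the replicate number as a block there were 1 gene in brain, 2213 in liver, 0 sites by the quasi-binomial model in liver, embryo-liver, liver-brain and muscle-testis (8494, 43089, 26425 and 91123 at an unadjusted p under 0.05), and 1 brain window; it moved no other count by over 1.5 times. The block also leaves fewer residual degrees of freedom, so a count of 0 does not show that groups are alike. The numbers were taken to pair muscle with testis and wild brain with wild liver. They leave farmed brain and liver open, although both were taken to pair with testis. They do not pair farmed with wild samples or embryos with tissues. In RRBS of farmed tissues every sample correlated best with its own number in another tissue, a hint from the data, not the design. Farmed and wild samples of the same number, which are different fish, did so in brain 1 and 2 and liver 2 and 3 as well. In RNA no set of numbers paired, with correlations of -0.218 to 0.636 between farmed and wild samples of a tissue.

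Leaving out each replicate gave 143 to 285 genes in brain, 688 to 1844 in the interaction, 0 to 1 sites in brain, 0 to 7 in liver, 8751 to 38349 in embryo-liver, 0 to 4361 in liver-brain, 0 to 29089 in muscle-testis, 0 to 1 brain windows and 0 to 2 sites in the CpG interaction. Without farmed liver 2, 38349 sites come from 229190 tested in place of 89927.

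The farmed-wild difference in mean methylation over each sample's own sites turned to 1.005 points in brain and 0.852 in liver, and that of liver and brain to -0.698 at a coverage of 20. Leaving out replicates it ran from -0.723 to 0.836 in brain, from -1.78 to -0.134 in liver and from -0.296 to 1.49 between liver and brain. Sites called without overdispersion gave an overlap of 363 and an embryo position of 48.7% at liver sites.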

Other observations

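The test of the embryo position used sites called without overdispersion, a choice of sites made only after the results were seen, as was the check of that test on farmed muscle and testis.

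Unplaced sequence held a large share of the sites that did not differ between tissues. It held 39.03% of the sites not called between embryos and brain, but 10.6% of those higher and 31.8% of those lower in embryos. Between liver and brain it held 52.2% of the sites not called, 9.89% of those higher and 19.4% of those lower in liver, and between muscle and testis 36.1%, 7.24% and 11.3%. These shares were not tested.

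The 10 most abundant genes took 36.4 ± 3.96% of the counts in muscle (SD, n = 5), 25.8 ± 1.57% in farmed liver (n = 5), 3.77 ± 1.41% in farmed brain (n = 5) and 4.21 ± 1.63% in testis (n = 7). Genes with at least 1 count were most numerous in testis, at 24264 ± 1183 of 26719, against 22724 ± 645 in farmed brain, 19353 ± 1480 in muscle and 19203 ± 533 in farmed liver, although testis and brain libraries differed in depth. These values were not tested.

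A hypothesis that origin shifts the same sites in brain and liver was tested by regrouping the same numbered fish in both tissues. The correlation across sites of the brain and liver differences was 0.187 for the real grouping. Of the 9 other groupings the highest gave 0.219, and values of 0.193 and 0.192 also lay above the real one. This meets the bar set beforehand against origin, that another grouping gives a correlation as high. The gap to the highest lies within the SD of the others (0.0348), a rule that was not part of that bar. The regrouping also takes equal numbers as the same fish, which is left open for farmed brain and liver. The test therefore does not single out origin. Whether origin or differences between individual fish underlie the correlation stays open.

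A hypothesis that embryos of captive spawners lie closer to farmed than to wild fish was tested in the same way at brain sites called without overdispersion. The pools were closer to the farmed mean at 48.2% of sites for the real grouping and at up to 57.2% for other groupings (SD of the others 6.22). This meets the bar set beforehand against the hypothesis, that another grouping gives a share as high. Muscle and testis of farmed fish, made with another kit, gave 51.7 and 50.3% for the real grouping and up to 57.9 and 60.8% for others. At brain sites the measure did not pick out captive fish either, although kit and tissue cannot be told apart there. At liver sites embryos gave 48.7% (up to 61.3% for other groupings), muscle 62.0% (up to 63.6%) and testis 64.0% (up to 64.6%), of which the tissues share their numbering with the livers used, and the hypothesis stays open.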
